A study of Mus musculus with 2 samples.

How the data were processed

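Total RNA of the gastrocnemius, the large calf muscle, was profiled in 2 male mice of a C57BL/6 by CAST F1 cross aged 36 days. Per the labels, the libraries were stranded and reduced in ribosomal RNA, started from 300 ng of RNA taken with a column kit, and held ERCC spike-in RNAs. The labels number the animals as biological replicates 1 and 2 of 1 tissue, so the series holds 1 group with n = 2 and no contrast between groups. Each replicate is a separate biosample with its own mouse number per the labels, although both carry the same donor entry. The spread between them was taken as that of 2 animals and can be partly technical. The files do not separate the parental alleles.

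Each library had a gene table and a pair of transcript tables. Per the file headers and the deposited notes beside them, the gene table and the first transcript table came from alignments to the transcriptome on mouse build mm10 with GENCODE annotation M21. The second transcript table came, per the same deposited notes, from the reads and an index. The aligner, the quantifiers and their versions are not given in the sources used here. The column layouts are those of RSEM for the gene and first transcript tables and of kallisto for the second transcript table. The authors deposited expected counts, which are estimated reads per gene and need not be whole. The deposited TPM values are relative transcript abundances, scaled by length, over all features listed, including tRNA genes and spike-ins in the gene table, and sum to the same total in each library. The authors also deposited a posterior mean TPM and the bounds of a credibility interval of TPM, whose level is not given in the sources used here. Deposited FPKM values, fragments scaled by effective length and library total, served only as an alternative. The deposited percent of each gene's expression carried by each transcript was recomputed here from the transcript TPM. In the first tables length minus effective length was that of a single 100-base read. In the second its median over long transcripts was 335 bases in replicate 1 and 340 in replicate 2. Short sequences had a smaller gap there, such as an ERCC sequence of 505 bases with an effective length of 180.1 in replicate 1. Nothing was pooled across animals.

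The gene table listed 81881 features, of which 55536 were Ensembl genes, 26248 were tRNA genes and 96 were ERCC sequences. All 55536 Ensembl genes were matched by versioned identifier to the M21 annotation, which gave symbols, types and coordinates (mm10, counted from 1). All 387 symbols in the 35 gene lists were found. Where several genes carried a symbol, the copy with the highest mean TPM was taken.

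Depth per library was 36952277 expected counts in replicate 1 and 38754338 in replicate 2. A count of 0 then allows up to 3 reads, or 0.0812 and 0.0774 CPM. Wilson 95% intervals are given for shares of a single library. These intervals, the floor and the deposited credibility intervals cover counting and read assignment only, and they leave out the spread between animals.

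A chi-square test of the rounded expected counts of 15022 genes gave a statistic of 35.2 per degree of freedom. The libraries therefore differed by more than sampling noise and were not 1 library deposited in duplicate. This does not tell separate animals from separate preparations of 1 RNA, and the count of 2 replicates rests on the labels. Levels are given as mean ± SD (n = 2). With 1 group of 2 animals no p-value can be had for any gene, and none is given.

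The comparisons, gene lists, criteria and the rule for named genes were fixed before the data were examined. Named genes were the 20 nuclear genes with the highest mean TPM, the adult myosin heavy chains, the 11 fast and slow paralog pairs and the 29 genes fixed for their splice forms. Of each list, up to 4 members were named: the pair with the highest mean TPM, the lowest, and the member with the largest absolute log2 ratio between the animals at a mean TPM of at least 1. The 10 largest and the 10 smallest log2 ratios among the genes past all criteria were also named. Ratios between animals are replicate 2 over replicate 1 on the log2(TPM + 0.1) scale, which understates ratios of low genes. A gene was said to differ when its mean expected count was at least 50, its TPM ratio at least 2-fold and its credibility intervals did not overlap. The intervals need not hold the TPM: Acta1 in replicate 1 had 22669 TPM and an interval of 22150 to 22246. Near-equal counts could also pass: Proser3, picked after its values were seen, had 80 and 75 expected counts. Its log2 ratio was -1.11, but -0.22 in the second transcript table. A list's median log2 ratio, over members with a mean TPM of at least 0.5, was placed among 10000 random lists of the same size, whose members were drawn within 50 ranks of mean expression. This percentile describes the libraries and is not a test over animals. Lists with fewer than 5 such members were not placed. The spread between the animals was the common dispersion of edgeR 4.0.16 (R 4.3.3) with an intercept-only design and TMM factors. It used expected counts rounded to whole numbers, of genes with at least 10 in both libraries. The SD of 50 bootstrap draws of genes is given with it and leaves out the sampling of animals. Sums per gene of the second transcript table were compared with the gene table. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

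The steps were tested on simulated data drawn with the means of the real genes, the measured spread and 200 changed genes. For the comparison of genes between the animals, with 11616 genes in the step, 50% of genes changed 2-fold passed the criteria, and 92% of those changed 3-fold did. Of 11416 unchanged genes, 145 passed as well. For the gene lists, 3 of 29 unshifted lists fell outside the central 95%, and a list shifted by 1.5-fold lay at percentile 100. A simulated spread of 16.9% was recovered as 16.6%.

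Alternatives replaced the gene table by the second transcript table, the posterior mean TPM or FPKM. Others rescaled TPM over subsets of features, changed the pseudocount, the filters or the normalization (DESeq2 1.42.0 size factors), or left out either replicate. A cubic trend of the log2 ratio on GC content and log2 length of each main transcript, fitted over 13028 genes, and a rescaling over nuclear protein-coding genes were added after the data were seen. Spike-ins were left out of the count of detected genes. The tRNA genes drew 0 reads in replicate 1 and 1 read in replicate 2 and entered no gene list. Some genes that the naming rule takes, and a test of the clock difference on output genes, which did not decide, are not reported here.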

Results

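Total RNA-seq of gastrocnemius was available from 2 male F1 mice of a C57BL/6 by CAST cross at 36 days of age. Replicate 1 had 36952277 expected counts and replicate 2 had 38754338. As the labels name a single tissue, age, sex and cross, the report gives the make-up of this muscle's transcriptome and how far the animals differed. Values are mean ± SD over the 2 animals (n = 2) unless a replicate is named, and coordinates are mm10.

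Nuclear protein-coding genes took 73.0% ± 0.297 of the expected counts. The mitochondrial ribosomal RNAs took 11.8% ± 0.409 and the mitochondrially encoded messenger RNAs 4.32% ± 0.518. Rn7s1 and Rn7s2 encode the 7SL RNA of the signal recognition particle and lie on chromosome 12 (69159295-69159594 and 69361182-69361481). Together they took 5.20% ± 0.619 of the counts but 30.9% ± 2.72 of TPM, because TPM divides by a very short effective length. In replicate 1 their share of counts was 5.64% (Wilson 95% interval 5.63 to 5.64) and in replicate 2 it was 4.76% (4.75 to 4.77). The pair carried identical values in each library, 164064 and 144837 TPM, so reads could not be told apart between the copies. Spike-ins took 0.571% ± 0.0613 of the counts, and 67 of 96 ERCC sequences had a read in both libraries.

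Among the 20 nuclear genes with the highest mean TPM, contractile and energy genes of muscle led after 7SL. Acta1, the skeletal muscle actin (chromosome 8, 123891769-123894751), stood at 23844 ± 1662 TPM. Mylpf, the fast regulatory light chain, stood at 19262 ± 516 TPM, and Ckm, the muscle creatine kinase, had 18408 TPM as its mean. Tnnt3 (13445 ± 148 TPM), Myl1 (12733 ± 15.3 TPM), Myh4 (11176 ± 817 TPM), Tpm1 (11046 ± 273 TPM), Atp2a1 (9096 ± 389 TPM), Tnni2 (7420 ± 17.3 TPM) and Tnnc2 (6903 ± 51.3 TPM) followed. Aldoa, the glycolytic aldolase, stood at 9664 ± 1693 TPM and Pvalb, a calcium buffer of fast fibres, had a mean of 8485 TPM. The list also held Rn7sk (11220 ± 599 TPM) and Gm26917 (5081 TPM). Gm28661, Gm28437, Gm10925 and Gm29216 are adjacent chromosome 1 pseudogenes (24613189-24616197) that copy mitochondrial DNA. They took 2.01% ± 0.226 of the counts, while the mitochondrial gene mt-Co2 was given only 132 ± 55.8 TPM. In the second transcript table Gm10925 had only 26.6 and 0.418 TPM, and mt-Co2 had 969 and 1161 TPM in replicates 1 and 2. The other copies stayed high there: Gm28661 had 20209.5 and 22528.5 TPM, Gm28437 13109.5 and 13995.6 TPM, and Gm29216 3292 and 3053 TPM. Levels of mt-Co2 and of these copies, and the share of the mitochondrially encoded messenger RNAs, are therefore uncertain.

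Myosin heavy chain genes are the usual guide to fibre type, and the adult set was almost wholly fast. Myh4, the IIB myosin, made up 87.2% ± 2.75 of the summed TPM of Myh4, Myh1, Myh2 and Myh7. Myh1, the IIX myosin, made up 8.41% ± 2.89, Myh2, the IIA myosin, 3.98% ± 0.0578, and Myh7, the slow myosin, 0.452% ± 0.203. The fast genes sit side by side on chromosome 11, with Myh4 at 67238029-67260446, and Myh7 lies on chromosome 14 (54970684-54994626). Myh1 was 1300 TPM in replicate 1 and 839 TPM in replicate 2, while Myh7 was 38.3 and 78.5 TPM. Of the 13 myosin heavy chains in the fixed list, 12 were detected in both animals, and the lowest was Myh7b at 0.660 ± 0.127 TPM. Neighbouring myosin genes have near-identical stretches, so some of their reads could have been split between them. In the second transcript table Myh1 made up 13.7% of the set.

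All 11 fast and slow paralog pairs had the fast member higher in both animals. The median log2 ratio of fast over slow was 7.37 ± 0.46 (SD of the animals' medians). The pair of troponin I genes had the largest gap, with Tnni2 over Tnni1 at log2 8.54 ± 0.71, and the troponin T pair, Tnnt3 over Tnnt1, was at 8.03 ± 0.74. Tpm1 over Tpm3 stood at 7.94 ± 0.59, Tnnc2 over Tnnc1 at 7.66 ± 0.75, Casq1 over Casq2 at 7.45 ± 0.20 and Atp2a1 over Atp2a2 at 7.37 ± 0.46. Myl1 over Myl3 was at 7.26 ± 0.71 and Mylpf over Myl2 at 7.11 ± 0.37. Gaps were smaller for the anchoring proteins Myoz1 over Myoz2 (3.91 ± 0.01) and Actn3 over Actn2 (3.07 ± 0.00). Actn2 is not among the fixed slow fibre genes, so the Actn3 and Actn2 pair need not compare fast with slow fibres. The myosin-binding proteins Mybpc2 over Mybpc1 had the smallest gap, 2.35 ± 0.56. In every pair the mean log2 ratio was larger than the SD of the animals. In 9 of the 11 pairs the ratio was smaller in replicate 2.

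**Figure D1:**
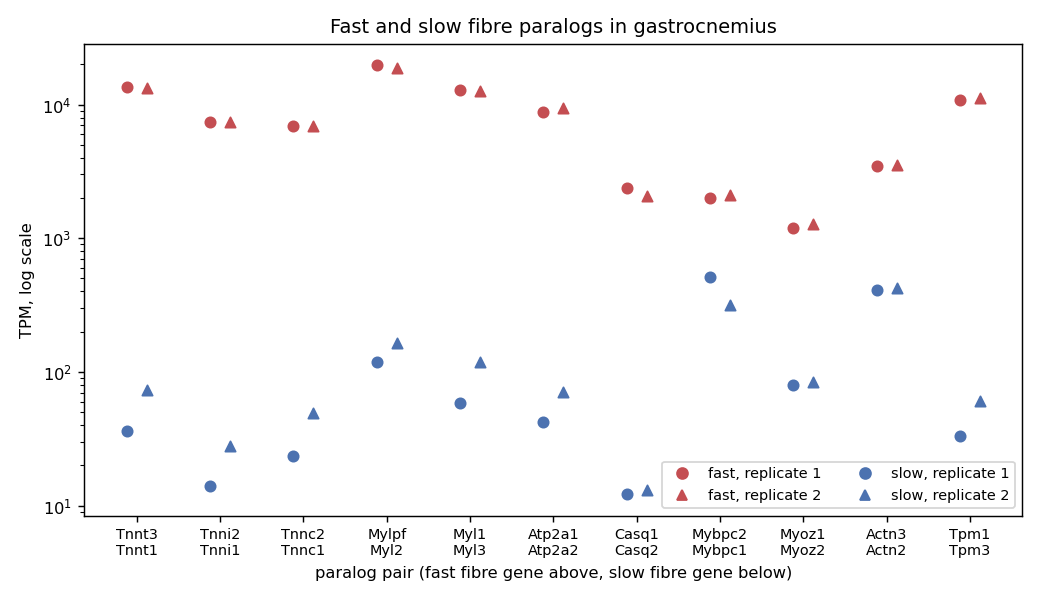
TPM (log scale) of each gene taken as fast (red) and its paralog taken as slow (blue) in replicate 1 (circles) and replicate 2 (triangles). The red symbols lie above the blue in all 11 pairs. Some slow genes, such as Tnnt1 (36.0 and 73.2 TPM), differ between the animals more than their fast partners, but Casq2 and Myoz2 differ less.

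The 13 fast fibre genes together held 98599 ± 47.0 TPM, or 9.86% of all TPM, and the 12 slow fibre genes 1050 ± 37.5 TPM. These sums depend on the features that TPM is scaled over and on the quantifier: the fast fibre genes had 162651 TPM in the second transcript table and 239282 when TPM was rescaled over nuclear protein-coding genes. All members of both lists were detected. The small SD of the slow fibre sum hides opposite shifts. Mybpc1, its largest member, had 511 and 314 TPM in replicates 1 and 2, while 10 of the 12 members were higher in replicate 2. The 15 sarcomere scaffold genes summed to 35251 ± 3133 TPM, led by Acta1 and by titin, Ttn (2301 ± 65.5 TPM). Actc1, the cardiac actin, was 891 TPM in replicate 1 and 1767 TPM in replicate 2, and Flnc was the lowest at 166 ± 3.89 TPM. The 19 glycolysis and glycogen genes summed to 29532 ± 4674 TPM, from Aldoa and Gapdh (4846 ± 701 TPM) down to Fbp2 (15.6 ± 4.19 TPM). In the second transcript table Gapdh had 14245 ± 3153 TPM, above Aldoa there (13520 ± 1446 TPM), so its level is uncertain. The 19 nuclear genes of the respiratory chain and citrate cycle summed to 6087 ± 775 TPM, led by Cox8b (685 ± 84.2 TPM) and Cox4i1 (606 ± 69.7 TPM), with Cycs lowest at 38.4 ± 2.73 TPM. Cycs had 515 and 532 TPM in the second transcript table, so its level is uncertain. The 13 mitochondrially encoded messenger RNAs summed to 54980 ± 8248 TPM, led by mt-Co1 (12993 ± 1955 TPM) and mt-Cytb (7304 ± 995 TPM). The chromosome 1 copy of mitochondrial DNA Gm28661 alone was given 13703 TPM as its mean, so the sum and the order of these RNAs are uncertain. Of these RNAs mt-Atp8 (3668 ± 638 TPM) and mt-Nd4l (4263 ± 25.2 TPM) had means of 0 and 38.7 TPM in the second transcript table. Their levels are uncertain. The 13 fatty acid genes summed to 1263 ± 302 TPM, led by the fatty acid binding protein Fabp3 (275 ± 91.8 TPM).

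Of the 18 genes of excitation and calcium handling, 16 were detected and the sum was 3510 ± 0.601 TPM. Ryr1, the calcium release channel (chromosome 7, 29003344-29125179), stood at 603 ± 4.19 TPM and Srl at 562 ± 1.55 TPM, whereas the calcium pump inhibitors Sln (0.0750 ± 0.0354 TPM) and Pln (1.25 ± 0.806 TPM) were near the bottom. The 11 neuromuscular junction genes summed to 83.2 ± 5.93 TPM, led by the kinase Musk (15.5 ± 0.764 TPM) and the acetylcholinesterase Ache (14.7 ± 2.87 TPM). Chrng, the fetal subunit of the acetylcholine receptor, was at 0.135 ± 0.106 TPM. The 11 dystrophin complex genes summed to 491 ± 5.90 TPM, from Sgca (102 ± 0.106 TPM) to utrophin, Utrn (10.7 ± 2.59 TPM). The 11 myogenic transcription factors were all detected and summed to 411 ± 6.12 TPM, led by Mef2c (132 ± 3.09 TPM) and Tead1 (59.7 ± 3.25 TPM). The 11 atrophy and growth genes summed to 311 ± 28.2 TPM, led by the ubiquitin ligase Trim63 (122 ± 19.4 TPM). The 10 heat shock genes summed to 1174 ± 27.7 TPM, with Hspa8 (495 ± 19.2 TPM) and Cryab (368 ± 62.8 TPM) highest.

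The 14 glucocorticoid and fasting genes summed to 1406 ± 337 TPM, led by Pdk4, the brake on pyruvate oxidation (590 ± 0.453 TPM). The 15 immediate early genes summed to 231 ± 86.7 TPM and the 15 circadian clock genes to 218 ± 54.7 TPM. Only 3 of the 12 interferon response genes were detected, with a sum of 12.4 ± 3.15 TPM. Of the 10 cell division genes only Top2a reached 1 TPM in both animals, at 1.17 ± 0.0141 TPM, and the list summed to 4.66 ± 0.877 TPM.

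Markers of cells other than muscle fibres were present at uneven levels. Fibroblast markers summed to 1390 ± 611 TPM, with the collagens Col1a1 (528 ± 286 TPM) and Col1a2 (337 ± 164 TPM) highest. Red blood cell markers summed to 329 ± 37.3 TPM, through the globins Hbb-bs (117 ± 13.4 TPM) and Hba-a1 (112 ± 13.4 TPM), which have near-identical copies and had 273 ± 35.6 and 281 ± 45.5 TPM in the second transcript table. Schwann cell markers summed to 231 ± 207 TPM, smooth muscle and pericyte markers to 184 ± 20.9 TPM, and tendon cell markers to 138 ± 42.0 TPM. Adipocyte markers summed to 123 ± 20.2 TPM, endothelial markers to 95.6 ± 8.68 TPM, macrophage markers to 63.3 ± 15.8 TPM and satellite cell markers to 43.6 ± 13.2 TPM. None of the 5 neutrophil markers reached 1 TPM. Among lymphocyte markers only Ighm, the immunoglobulin mu constant region (chromosome 12, 113418558-113422730), did, at 61.1 ± 0.156 TPM. The B cell gene Cd79b was at 0.105 ± 0.0212 TPM, and Nkg7 was listed at 0. Heart markers summed to 15.6 ± 5.61 TPM, nearly all from Myh6 (12.3 ± 5.81 TPM), which shares sequence with Myh7, and from Tnnt2 (2.18 ± 0.00707 TPM). Of the liver and skin markers only Krt10 reached 1 TPM, at 1.43 ± 0.0424 TPM, and Alb was listed at 0.

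The 4 Y-linked genes were all detected and summed to 46.4 ± 1.80 TPM, led by Ddx3y (21.2 ± 0.948 TPM), while Xist, the RNA of the inactive X, was at 0.01 TPM in each animal, as the male labels state. Of the 20 imprinted genes 18 were detected, with a sum of 1668 ± 208 TPM. H19, an imprinted noncoding RNA (chromosome 7, 142575529-142578143), stood at 909 ± 132 TPM and Gnas at 520 ± 12.3 TPM. The 10 noncoding RNAs of the fixed list summed to 16437 ± 1501 TPM, of which Rn7sk and Rpph1, the RNA of ribonuclease P (2811 ± 657 TPM), made up most. The second transcript table listed Rn7sk at 0 and Rpph1 at 1.04 and 1.53 TPM, and the list summed to 984 TPM there, so these levels are uncertain.

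In all, 10893 genes reached 1 TPM in both animals, of which 10041 were protein-coding, and 902 others did so in a single animal. Over 11390 genes with a mean of at least 1 TPM, log2 TPM of the animals had a Pearson r of 0.966 and a Spearman rho of 0.970 across genes, which are not independent replicates. Of these genes 96.6% lay within 2-fold. The biological coefficient of variation between the animals was 16.9% ± 0.341 (bootstrap SD over genes, not animals) over 14518 genes.

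Among genes past the criteria for single genes, the lowest ratio of replicate 2 over replicate 1 belonged to Cish. This gene, a feedback inhibitor of cytokine receptors (chromosome 9, 107296026-107302784), was 46.5 TPM in replicate 1 and 1.59 TPM in replicate 2, a log2 ratio of -4.79. Gadd45g, a stress-induced gene, was 40.7 and 3.25 TPM (log2 ratio -3.61), and Ddit4, an inhibitor of mTOR signalling, was 85.8 and 7.39 TPM (log2 ratio -3.52). Socs3, another cytokine feedback inhibitor, had a log2 ratio of -2.61, Csrnp1 of -2.60 and the potassium channel gene Kcnf1 of -2.70. AC154912.3 (-3.79), E230001N04Rik (-2.99), Gm38034 (-2.87) and Gm20425 (-2.81) completed the 10 lowest log2 ratios. Gm20425 had a log2 ratio of only -0.91 in the second transcript table.

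Higher in replicate 2 were Dbp, a clock-driven transcription factor (4.34 and 21.4 TPM, log2 ratio 2.27), Gsdma3 (log2 ratio 2.13), Tbx1 (1.99), and G0s2, an inhibitor of fat breakdown (1.82). The others among the 10 highest were 0610040J01Rik (1.73), Gm49759 (1.61), Mettl11b (1.53), Igfn1 (1.49) and Ybx2 (1.45), the last with a log2 ratio of only 0.28 in the second transcript table. Mup22 had the highest ratio (2.63) but belongs to a family of near-identical genes and was listed at 0 in the second transcript table, so it is uncertain. Of 11665 genes with enough counts, 257 passed all criteria, 205 of them higher in replicate 1 and 52 higher in replicate 2. The number was 125 with pseudocount 1, 140 at a mean count of at least 200 and 395 without a filter. In simulated libraries given 1 common spread for all genes, 145 of 11416 unchanged genes passed. That spread, 16.9%, was taken from these same libraries with the differing genes included, and was 14.7% at counts of at least 100. Intervals in the simulation covered counting only. Part of the 257 may be within the spread between animals, but how many cannot be told. With a single animal on each side the differences have no replicate check.

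Whole gene groups also stood apart between the animals. Of 29 lists placed among random lists, 16 lay outside the central 95%, 8 higher in replicate 2 and 8 higher in replicate 1, where chance gives 1.45 and 3 of 29 unshifted lists lay outside in simulated libraries. The genes of a list can vary together in an animal, so these percentiles describe the libraries only.

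The Schwann cell markers had the lowest median log2 ratio, -1.75 (random lists -0.29 to 0.20), with all 9 members lower in replicate 2 and 8 past the criteria for single genes. The myelin gene Mbp (137 and 30.2 TPM) had a log2 ratio of -2.18, and the Schwann cell cadherin Cdh19 had -1.07. Tendon cell markers followed at -1.07 (random lists -0.20 to 0.18), with all 8 members lower in replicate 2, from Mkx (-1.77) to Thbs4 (-0.20). Macrophage markers stood at -0.60 (10 of 10 lower in replicate 2, with Csf1r at -0.96) and fibroblast markers at -0.59 (9 of 9 lower, with Col1a1 at -1.16 and Pdgfra at -0.43). Adipocyte markers lay on the other side, at 0.82 (random lists -0.27 to 0.26), with all 7 tested members higher in replicate 2, among them Cfd (0.82) and Pck1 (1.24). Without a filter the adipocyte list had 8 members, 7 higher and 1 lower in replicate 2, and a median of 0.81. Medians of satellite cell (0.05), endothelial (0.06), smooth muscle and pericyte (0.02) and red blood cell markers (-0.23) lay inside their random ranges. With members of at least 5 TPM, too few Schwann cell and adipocyte markers were left to place those lists.

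The immediate early genes had a median of -0.97 (random lists -0.16 to 0.17), with 13 of 14 tested members lower in replicate 2. The nuclear receptor gene Nr4a3 (-2.51), its relative Nr4a1 (-0.83) and the phosphatase gene Dusp1 (-0.57) were among them. The glucocorticoid and fasting list had a median of -0.24 (random lists -0.09 to 0.19), which rested on 10 of 14 members. At a mean TPM of at least 5 it was -0.40 (10 of 13 members lower), and in the second transcript table -0.34 (14 of 14 lower). Its metallothionein Mt2 (-2.34) and Ddit4 (-3.52) were lower in replicate 2, whereas Pdk4 (-0.00) and Angptl4 (0.06) had near-equal levels. Imprinted genes stood at -0.48 (15 of 20 lower in replicate 2), with H19 at -0.30, Mirg at -0.92 and Gnas at -0.05. The noncoding RNAs had -0.22 (6 of 7 lower), just outside their range (-0.18 to 0.31), moved inside it in the second transcript table and under both other filters, and had -0.35 after rescaling over nuclear protein-coding genes. Other short RNA classes also took a smaller share of counts in replicate 2: small nuclear RNAs 0.129% and 0.0802% in replicates 1 and 2, small nucleolar RNAs 0.0416% and 0.0286%, and microRNA genes 0.00217% and 0.00119%.

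The slow fibre genes had a median of 0.81 (random lists -0.09 to 0.17), with 10 of 12 members higher in replicate 2. In the second transcript table it was 0.52, with 9 of 12 higher. Myh7 (1.03), Tnnt1 (1.02), Tnni1 (1.00), Tnnc1 (1.04) and Myl3 (1.01) all stood about 2-fold higher in replicate 2, and Tpm3 (0.88), Atp2a2 (0.74) and Myl2 (0.47) less so. Casq2 (0.10) and Myoz2 (0.08) were near equal. Mybpc1 (-0.70) and the muscle LIM protein gene Csrp3 (-1.27) were lower in replicate 2. The fast fibre genes had a median of -0.00, inside their random range, although Myh1 was at -0.63. Their median was -0.11, outside its range, in the second transcript table. All myosin heavy chains together (0.06) also lay inside their range.

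Genes of fuel use were higher in replicate 2 by smaller steps. Fatty acid genes stood at 0.47 (13 of 13 members higher), with Fabp3 at 0.69 and Slc25a20 at 0.44. Glycolysis and glycogen genes stood at 0.32 (19 of 19), with Aldoa at 0.36 and Phka1 at 0.59. Nuclear respiratory chain and citrate cycle genes stood at 0.28 (19 of 19), with Cox7a1 at 0.38 and Cycs at 0.14, though at 0.18 (17 of 19) in the second transcript table, and the mitochondrially encoded messenger RNAs at 0.37 (11 of 13), with mt-Co1 at 0.31 and the uncertain mt-Co2 at -0.89. None of the members of these lists passed the criteria for single genes. The circadian clock list had a median of 0.61 (random lists -0.17 to 0.15), with 10 of 15 members higher in replicate 2 and 5 lower. Dbp (2.27), Nr1d1 (0.93) and Tef (0.57) were among the higher members and Npas2 (-1.44) among the lower. The interferon response list stood at 0.58 over 6 members of low level, such as Bst2 (0.32). It had 0.34 with pseudocount 1, 0.88 over 10 members after rescaling over nuclear protein-coding genes and 0.85 over 12 members without a filter. The list moved inside its range, to 0.15, in the second transcript table, and at a mean TPM of at least 5 too few members were left to place it.

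Other lists lay inside their random ranges. These were the sarcomere scaffold (0.19, with Actc1 at 0.99), neuromuscular junction (0.13, with Colq at 1.03), heat shock (0.05, with Dnajb1 at -0.40), excitation and calcium handling (0.02, with Pln at 1.30), myogenic transcription factors (0.01, with Myog at -1.02 and Six4 at 0.58), dystrophin complex (-0.01) and atrophy and growth lists (-0.11, with Fst at -1.63). In the second transcript table the atrophy (-0.44) and neuromuscular junction lists (0.10) lay outside their ranges. The atrophy list also lay outside after adjustment for GC content and length (-0.12).

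**Figure D2:**
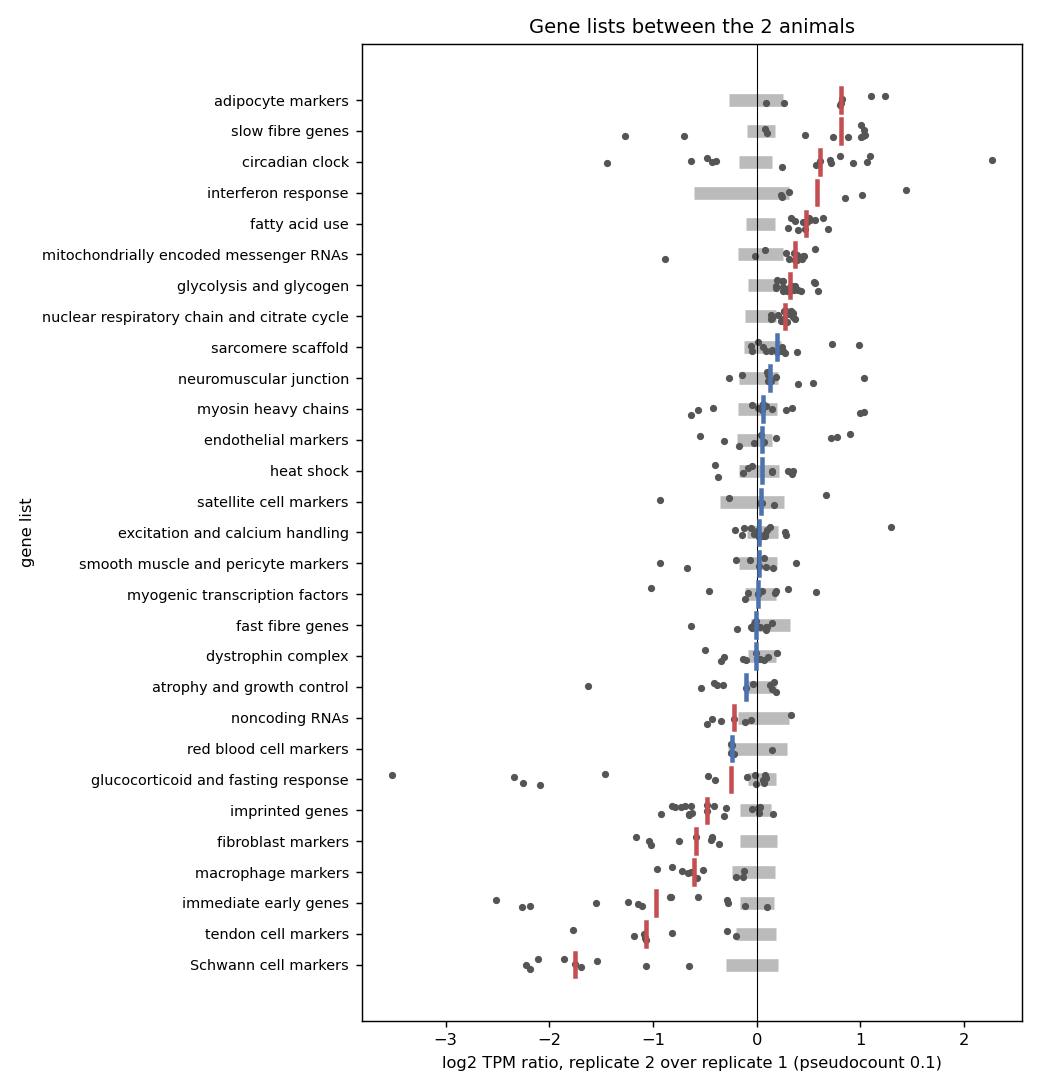
Log2 TPM ratio of replicate 2 over replicate 1 for the members of each gene list (dots), the list median (red where outside and blue where inside the grey bar) and the central 95% of medians of matched random lists (grey bar). Schwann cell markers lie lowest, at a median of -1.75, and adipocyte markers and slow fibre genes highest, at 0.82 and 0.81.

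Across the 29 genes fixed for their splice forms, the main transcript carried a median 54.4% ± 0.705 of the gene's TPM. Atp2a1-201, a form of the fast calcium pump, carried 99.6% ± 0.183, Tpm1-205, a form of tropomyosin, 97.3% ± 0.259, and Ryr1-202 94.7% ± 1.18. Ldb3-207 carried 78.8% ± 1.51 of the Z-disc gene Ldb3, Bin1-205 78.3% ± 1.29 of the tubule gene Bin1, and Fxr1-201 69.4% ± 1.84. Dmd-203 carried 65.2% ± 1.41 of dystrophin, Cacna1s-204 63.4% ± 1.63, Pdlim3-203 61.4% ± 1.30 and Camk2b-209 60.6% ± 2.67. Shares were spread over many forms in Mef2c (Mef2c-201, 45.5% ± 1.36), Mef2d (Mef2d-201, 43.0% ± 1.35), Tpm2 (Tpm2-202, 43.5% ± 0.560), Nfix (Nfix-204, 41.4% ± 1.13), Camk2g (Camk2g-202, 36.1% ± 1.54) and Dtna (Dtna-201, 34.6% ± 0.297). Mybpc1-202 carried 53.0% ± 4.83, Clcn1-201 52.8% ± 3.63 and Atp2a2-202 69.1% ± 4.26. Ppargc1a-203 carried 36.4% in replicate 1 and 41.5% in replicate 2. The animals differed most for Tpm3, where Tpm3-205 carried 67.2% in replicate 1 and 86.4% in replicate 2. Both animals had the same main transcript for 27 of the 29 genes, Neb and Ppargc1a being the exceptions.

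The transcript tables named the same main transcript for 21 of the 29 genes. For Tnnt3 the first gave Tnnt3-201 a share of 45.8% ± 2.47 and the second gave it 0 and Tnnt3-225 45.3% ± 2.42. For Myl1 the first gave Myl1-202 71.2% ± 0.677 and the second 26.6% ± 5.33, and for Trdn the first gave Trdn-205 40.1% ± 0.524 and the second 9.97% ± 1.33. Pkm-202 had 54.4% ± 0.705 in the first and 44.3% ± 0.841 in the second. Tnnt1, Ttn, Neb and Mbnl1 also had other main transcripts in the second table. Shares also moved in genes that kept their main transcript: the second table gave Cacna1s-204 90.9% ± 1.13, Tpm1-205 75.2% ± 0.117, Bin1-205 59.0% ± 2.87 and Camk2g-202 24.6% ± 1.27.

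Spearman's rho across genes was 0.854 in replicate 1 and 0.853 in replicate 2, and Pearson's r of log2(TPM + 0.1) was 0.911 and 0.914, over 25998 and 25630 genes that are not independent replicates. In replicate 1, 49.7% of genes lay within 1.5-fold and in replicate 2 59.4% did, since the second table had a median TPM 1.46-fold and 1.36-fold that of the gene table. Against that median 78.8% and 78.5% lay within 1.5-fold. Rn7s1 had 1.13 and 0.553 TPM in the second table, Rn7sk was listed at 0, and 7SL in all took 0.000169% of its TPM. Of 51 genes shorter than 350 bases with at least 500 expected counts in replicate 1, 45 kept less than 10% of their counts in the second table, and of 49 in replicate 2 there were 44. Genes of 2000 bases or longer had a median count ratio of 1.10 in replicate 1 and 1.08 in replicate 2.

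**Figure D3:**
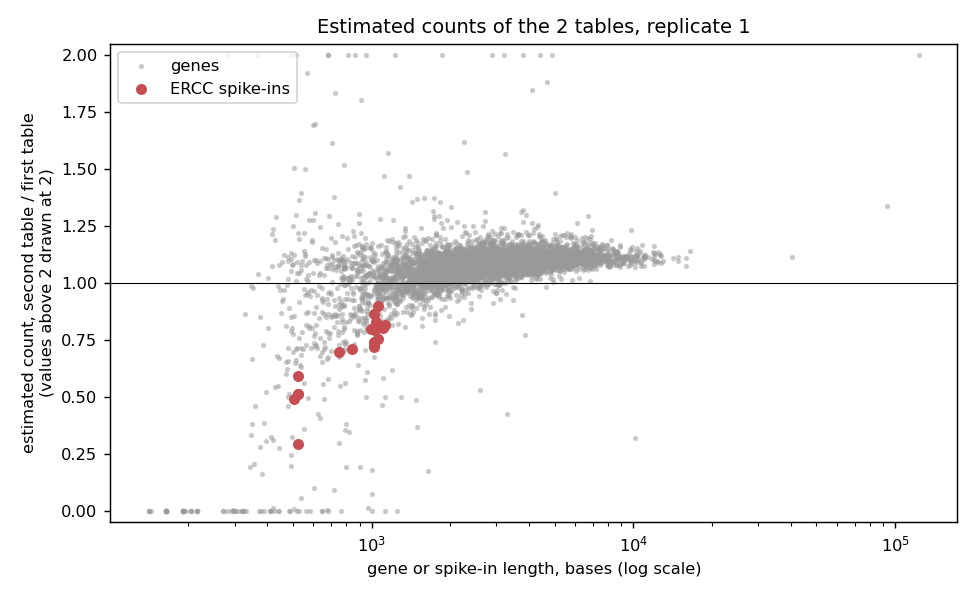
Ratio of the estimated count in the second table to that in the gene table against length in bases (log scale) in replicate 1, for genes (grey) and ERCC spike-ins (red) with at least 500 expected counts. Ratios of the shortest genes lie near 0, those of spike-ins between 0.295 and 0.899, and those of genes of at least 2000 bases around 1.10.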

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

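The rescaling over nuclear protein-coding genes and the adjustment for GC content and length were chosen after the data were seen. The second transcript table moved the Myh4 share to 82.2% of adult myosin, the fast fibre sum to 162651 TPM and the median main transcript share to 52.7%. The fast fibre sum was 96566 with posterior mean TPM, 119944 over non-mitochondrial, non-spike features, 82434 as FPKM and 239282 over nuclear protein-coding genes. Genes detected numbered 6229 at 5 TPM. Without either replicate in turn, the Myh4 share ranged from 85.2% to 89.1%, the median paralog log2 ratio from 7.05 to 7.70 and genes detected from 11243 to 11445. The spread between the animals was 17.6% with library size alone, 18.1% without a filter and 14.7% at counts of at least 100. Genes that differ numbered 125 with pseudocount 1, 395 without a filter, 140 at a mean count of at least 200 and 329 by fold alone. By fold alone there were also 459 in the second transcript table (211 of the 257 among them) and 407 over nuclear protein-coding genes, to be set against the 329. Between 76.5% and 89.3% of the genes were higher in replicate 1 in every setting. Pearson's r of the tables was 0.933 with pseudocount 1 and 0.748 for genes of at least 1 TPM.

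The fast member led in the median pair under all alternatives, between 7.05 and 7.70. Lists outside the random range numbered 12 to 17 of those placed, against 16. In the second transcript table, whose median gene had a log2 ratio of -0.11 against 0.00 in the gene table, the fast fibre (-0.11), neuromuscular junction (0.10) and atrophy lists (-0.44) moved outside their ranges, and the interferon (0.15) and noncoding lists (-0.17) inside. The adjustment for GC content and length moved the atrophy list outside (-0.12). The cause was not tested. No list outside its range changed direction. Of the 12 interferon genes 3 had a mean count of at least 50, and no alternative varied the depth.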

Other observations

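The genes described here before the weighed patterns, other than those named already, were picked after their values were seen, and all tests in this part were chosen after the results they weigh were seen. The design names no biological explanation for a difference between the animals, so none was tested.

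Beside Cish and Socs3, the related feedback inhibitor Socs2 was past the criteria, with a log2 ratio of -1.10. Other genes higher in replicate 1 were the coactivator gene Ppargc1a (-1.13), the kinase gene Sik1 (-1.30), the mitochondrial carrier gene Slc25a25 (-1.64, mean 59.8 TPM) and the calcineurin regulator Rcan1 (-1.44). Collagens typical of cartilage or the tendon insertion, Col2a1 (-1.68), Col11a1 (-1.64) and Col11a2 (-1.19), were higher in replicate 1 with the tendon markers. Car3, the carbonic anhydrase of fat and slow muscle, was 683 TPM in replicate 1 and 194 TPM in replicate 2, although slow fibre and adipocyte lists were higher in replicate 2. Genes higher in replicate 2 included the glucose-responsive Txnip (1.26, mean 178 TPM), the polyamine enzyme gene Smox (1.16, mean 117 TPM) and the triglyceride synthesis gene Dgat2 (1.35).

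Ighm was alike in both animals, 61.2 and 61.0 TPM, and in the second transcript table (83.3 and 76.0 TPM). Igkc, the kappa light chain, had 0 and 0.0700 TPM, Jchain 0.1 and 0.12 TPM and Cd79a 0.02 and 0.05 TPM.

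Schwann cell genes were lower in replicate 2, and removal of a trend with GC content and length, which held 0.914% of the variance of the ratios, left their median at -1.76, which argues against that trend as the whole cause. A lower share of fibre RNA in replicate 1 would raise markers of all other cell types there. The tendon (-1.07), macrophage (-0.60) and fibroblast (-0.59) medians went that way. The adipocyte median, however, lay 2.57 (log2) above the Schwann cell median, and the endothelial median was 0.06. All these medians were known when the comparison was chosen, so it cannot exclude a lower fibre share as part of the cause. A larger piece of nerve in the replicate 1 sample remains open as a hypothesis: of 12 further nerve genes 10 were lower in replicate 2, and the 10 of enough level had a median of -0.90 (random lists -0.41 to 0.27). Among them Cldn19 (-1.92) and Gldn (-1.17) had already been seen past the criteria and Mag had -1.33, while L1cam (0.41) and Art3 (0.04, at 153 TPM a gene this tissue also expresses) did not follow. How the muscles were dissected is not given in the sources used here.

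Clock genes moved apart between the animals: 9 genes of the Dbp phase had a median of 0.80, and the activators Arntl, Clock and Npas2 with Cry1 had -0.55. This gap of 1.36 was 1.33 after removal of the trend with GC content and length, which argues against that trend as the whole cause. The gap was seen and measured on the same genes, and Per1 and Cry2 of the fixed list entered neither group. Of the 15 members of that list 10 were higher and 5 lower in replicate 2. What set the groups apart stays open, and the time of dissection is not given in the sources used here.

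Short RNAs were nearly absent from the second table although it listed 100% of those with at least 500 counts, so missing entries are excluded. Counting a single strand would lower all lengths alike, but genes of at least 2000 bases had a median count ratio 0.357 above that of the spike-ins. That gap is not one of length alone, as genes of 350 to 2000 bases had median ratios of 1.03 and 1.02. Genes shorter than 350 bases had a median ratio of 0 in each replicate. A loss of reads where the transcript leaves no room for the assumed fragment may account for it: over 18 and 17 spike-ins the ratio rose with length (mean Spearman's rho 0.869 across sequences). It also lay within a median 0.0495 and 0.0534 of the ratio of the effective lengths. Protein-coding genes of 350 to 700 bases with a single annotated transcript had a median ratio of 0.479 (16 genes) and 0.453 (14 genes), against 0.961 and 0.940 for those with several, but single-transcript genes of 700 to 2000 bases had 0.958 and 0.934, above the spike-in medians of 0.733 and 0.732.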
